A study of Drosophila melanogaster with 2 samples.

How the data were processed

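The series holds 2 samples of wing discs from wandering-stage larvae, 1 per genotype. Per the labels' protocols, larvae were kept at 25 °C in a cycle with 12 h of light, and discs were dissected in sessions of 2 h into a phenol-based reagent. Discs were pooled to 80 to 100 per genotype before RNA extraction. A library was made from 4 µg of total RNA after removal of ribosomal RNA, with the TruSeq version 2 kit, and sequenced on a HiScan instrument. Samples were grouped by the genotype label into GFP and GFP_Tai.

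The submitters' processing notes name CASAVA 1.4, TopHat2 2.0.12, Cuffdiff 2.2.1 and the genome build dm6, without saying what each was used for. The annotation, the filters and the way replicates were combined are not given in the sources used here. The deposited table gives 1 FPKM value per gene and genotype, in the column layout of Cuffdiff (the file's name calls them RPKM), scaled by the authors. Per the file headers, the authors also gave a p-value and a q-value per gene and a call. The authors' log2 fold changes were not used, because 495 of them held spreadsheet error text where the GFP_Tai value was 0. They were recomputed from the FPKM values, and the 9524 finite ones differed by at most 4.95e-05. The loci of the table did not lie on dm6. Their starts differed from the BDGP6 annotation by a nearly constant offset per chromosome arm (4112496 bp on 2R, for example), and 177 genes lay on sequences that dm6 names otherwise. Coordinates were therefore taken from the BDGP6 annotation (Ensembl release 115) by gene symbol or synonym. Of 13989 genes, 13708 matched and 13441 also lay at the matching place on their arm.

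Differences were computed as log2((GFP_Tai FPKM + 1) / (GFP FPKM + 1)), which understates the difference of low genes. Genes with an FPKM of at least 1 in either genotype were kept (8275 genes), and a gene was counted as higher or lower at a 2-fold difference on this scale. With 1 value per genotype no test of the genotypes was made, and the authors' p-values and calls (q under 0.05) are given as in their deposited table. Ratios given beside genes are plain FPKM ratios. For 40 gene lists fixed before the data were examined, covering signaling and immune pathways, markers of other tissues and gene families, the median difference was computed. It carries an exact 95% interval from order statistics and its percentile among 10000 random lists of the same size, matched in 10 bins of mean expression. The medians of 5 lists are given only here. Matrix and adhesion had 0.15 (percentile 99.9) and glycolysis 0.14 (percentile 99.6). Oxidative and xenobiotic enzymes had -0.16 (percentile 3.21) and sex of the larvae 0.05 (percentile 78.8). Neurons had 0.30 over 4 genes (percentile 69.5). That median was -0.33 at a minimum FPKM of 5, where elav alone was left, and 0.13 to 0.44 in the other settings. The lists of mitochondrial genome, ribosomal RNA and transposon genes matched 0 genes of the table and were not analysed here. Enrichment of lists is given as shares of genes. The planned Fisher's exact tests were computed over genes, which are not replicates, so their p is not printed.

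Depth was estimated from the low values. Among genes above 0 in both genotypes, 304 had the same ratio of 0.765 (to 4 significant digits), taken as equal numbers of fragments in both libraries. Of 1355 untested genes above 0 in both, 75.2% lay within 0.0001 of a ratio of whole numbers up to 15 times this factor, against at most 0.59% with a shifted factor. With 215 nt taken off each transcript length, the step of 1 fragment, from 72 single-transcript genes at that ratio, gave 8127270 and 10619241 fragments for GFP and GFP_Tai. Of low single-transcript genes, 75.7% and 74.9% then came out whole within 0.1, where chance gives 20%. Since not all did, the fragments are estimates, used only for counting intervals (exact, from the binomial split of the fragments) and not for a count test. The intervals cover counting error only.

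Genes named in the text followed a rule fixed before the data were examined: tai, the genes with the largest differences among the authors' calls, up to 4 members of each list with the largest absolute difference, and en, inv, hh, ci, ptc, spz, Tl, cact, dl, Dif, rpr, hid, grim and Diap1. All 11 calls were named because they were few. Other genes are said to have been chosen after their values were seen.

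The computations were tested on simulated data, with fragments drawn for 9331 genes from their means and the estimated depths and 200 genes changed. For GFP_Tai against GFP, 38% of 50 genes changed 2-fold upward passed the 2-fold threshold, as did 100% of those changed 4-fold and of those changed 8-fold, and 98% of those at 0.25 times. Of 7624 unchanged genes, 30 passed. A planted list of 20 genes at 1.5-fold lay at percentile 100, and 50 unplanted lists had a median percentile of 50.2. The unit ratio and depth were recovered, but from whole fragments drawn with the same step, ratio and length offset. Values that are not whole, as in the data, were not simulated, so this checks only the computation.

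Alternatives were a pseudocount of 0.1 or 5, centring, no filter or a minimum FPKM of 5, thresholds of 1.5-fold and 3-fold, and the authors' q under 0.01. For the test of counting error in the cuticle and Osiris lists, a first bound (a share above 50% of the members above the minimum) was replaced, after the values were seen, by a share above 2.5% of all members. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.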

Results

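Gene expression was measured by RNA sequencing in wing discs, the larval epithelia that form the adult wing and part of the thorax, of wandering-stage Drosophila melanogaster larvae. The control genotype (GFP) expressed green fluorescent protein under the engrailed driver, which is active in the posterior compartment of the disc. The second genotype (GFP_Tai) expressed Taiman (Tai), a transcriptional coactivator of the ecdysone receptor, in addition to GFP. RNA came from a pool of 80 to 100 discs per genotype, so each value averages over whole discs, including the anterior cells. The data comprised 1 sample per genotype and 1 FPKM value per gene and genotype for 13989 genes. The series design speaks of triplicates, but no separate replicate values were analysed here, so no difference below has a replicate check. The depth was estimated from the low values at 8127270 fragments for GFP and 10619241 for GFP_Tai.

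The first comparison asked whether the libraries carried the expected genotype. The tai gene (FBgn0041092, 2L:9166778-9250211 in BDGP6, plus strand) had an FPKM of 27.1 in the GFP library and 879 in the GFP_Tai library. The ratio was 32.4, with a 95% counting interval of 30.9 to 34.0, from an estimated 1765 and 74767 fragments. The log2 difference was 4.97 on the log2(FPKM + 1) scale. In the authors' deposited table, tai had p = 0.0002 and was called. The posterior genes of the driver's own compartment had ratios nearer to 1. In GFP and GFP_Tai, the engrailed gene en had FPKM 43.2 and 46.8, and its paralog inv had 39.0 and 53.2. The ligand gene hh had 39.8 and 52.2. All 3 were higher in GFP_Tai, with a median log2 difference of 0.38 (percentile 98.7). The 95% counting interval of the ratio was 0.99 to 1.18 for en, 1.26 to 1.47 for inv and 1.19 to 1.44 for hh. In the anterior compartment, ci had FPKM 128 and 126, and the Hedgehog receptor gene ptc had 54.0 and 47.0 (median of the 4 listed genes -0.07).

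The second comparison asked which transcripts differed between discs with and without Tai expression. Many genes for cuticle proteins, the Osiris family of insect epithelial membrane proteins and ecdysone-response genes had higher values in the GFP_Tai library. Osi7 had an FPKM of 0.248 in GFP and 1133 in GFP_Tai, and Osi6 had 0.0925 and 513. The cuticle gene Lcp65Ad was listed at 0 in GFP and had 418 in GFP_Tai. Genes outside these groups differed too, among them CG12164 (FPKM 0.313 and 507, ratio 1621, 95% counting interval 594 to 8417, from an estimated 3 fragments in GFP) and CG1850 (2.67 and 924), both named after their values were seen. Small nucleolar and small nuclear RNAs made up 77 of the 150 genes at least 2-fold lower in GFP_Tai. Most other genes lay close to equal values.

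Of 8275 genes with an FPKM of at least 1 in either genotype, 522 were at least 2-fold higher in GFP_Tai and 150 at least 2-fold lower, on the log2(FPKM + 1) scale. At 4-fold the numbers were 240 higher and 73 lower. Without the list of small nucleolar and small nuclear RNAs, a choice made after seeing the data, 512 genes were higher and 73 lower. Among protein-coding genes, 496 were higher and 62 lower. The median log2 difference of all these genes was -0.02, and 86.2% lay within 1.5-fold. Across genes, which are not independent replicates, the libraries had a Pearson r of 0.895 on the log2(FPKM + 1) scale and a Spearman rho of 0.919. Low expression held most of the higher genes. The quartile of genes with the lowest mean FPKM held 321 higher and 54 lower genes, and the next quartiles held 81 and 21, 54 and 19, and 66 and 56. Counting error at the estimated depths gave far fewer such genes. In 100 simulated library pairs without a difference, on average 11.6 genes were higher and 10.3 lower, and at most 19 in either direction. The same 7926 genes held 500 higher and 73 lower genes in the data. Genes without a fragment estimate, among them short small nucleolar RNAs, were left out, so counting error was not assessed for them.

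**Figure D1:**
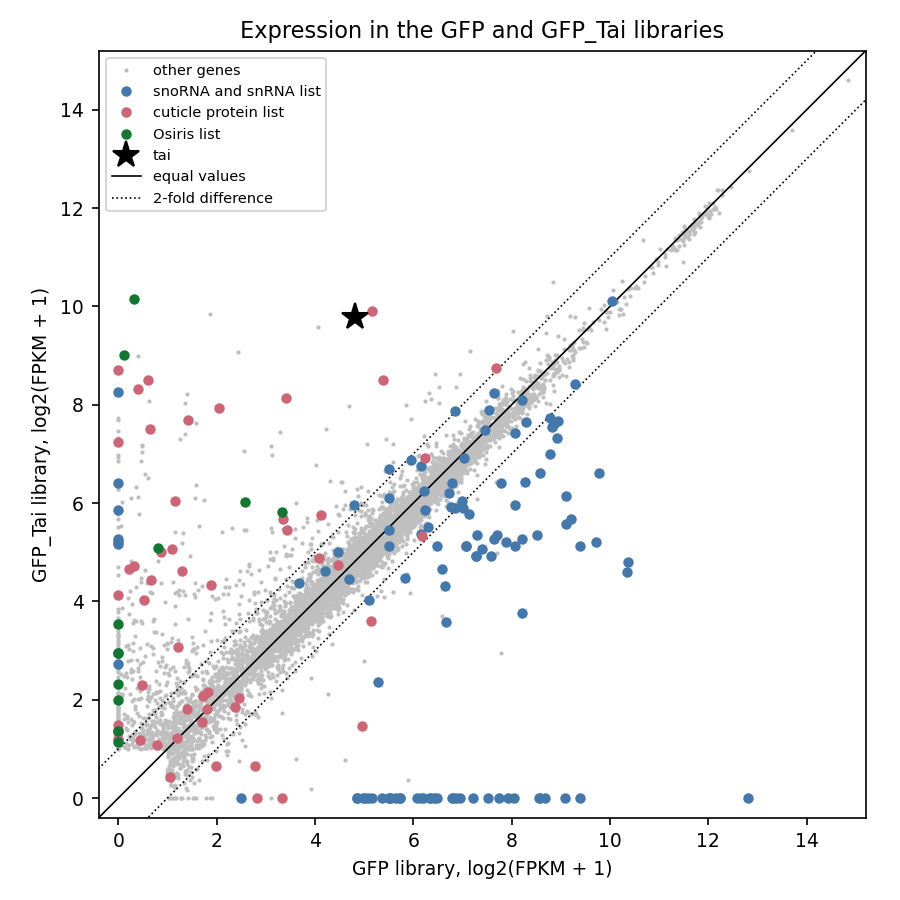
Expression of genes with an FPKM of at least 1 in either genotype, as log2(FPKM + 1) in the GFP library (x axis) and the GFP_Tai library (y axis). Each point is 1 gene, the solid line marks equal values and the dotted lines a 2-fold difference. Points of the cuticle protein and Osiris lists lie mostly above the upper dotted line, as does tai (FPKM 27.1 and 879), and many points of the snoRNA and snRNA list lie below the lower one.

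The authors' deposited table tested 8374 genes and called 11 of them, all with a higher value in GFP_Tai. Apart from tai, the 10 called genes were listed at 0 in GFP. In the authors' deposited table, the cuticle gene Lcp65Ad (FBgn0020641, 3L:6143395-6144101 in BDGP6) had 418 in GFP_Tai and p = 5e-05, and the cuticle gene Edg84A (FBgn0000552, 3R:6684445-6685157) had 149 and p = 5e-05. The other called genes of the authors' deposited table included the serine protease genes Jon65Aiv with an FPKM of 121 in GFP_Tai, Jon65Aiii with 85.0 and yip7 with 77.1. The remaining called genes carried only annotation numbers: CG15213 (206), CG42834 (176), CG33333 (159), CG14332 (147) and CG10910 (22.3), with FPKM in GFP_Tai in parentheses. In the authors' deposited table, 39 tested genes had a p under 0.05, where uniform p values would give 418.7, and the median p was 0.84. An exact 0 can be a failed estimate in such a table. The 7SL RNA gene, which every cell uses, was listed at 0 in both genotypes (named after its values were seen), so no ratio is given against a listed 0. The counts and list medians on the log2(FPKM + 1) scale do include such genes, and by construction any gene at 0 in 1 genotype that passes the minimum of 1 is at least 2-fold different. Among genes above 0 in both genotypes, 390 were at least 2-fold higher and 96 lower.

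The cuticle protein list had 51 genes above the minimum. Of these, 30 were at least 2-fold higher in GFP_Tai and 6 at least 2-fold lower, with a median log2 difference of 1.48 (95% interval of the median 0.68 to 3.11). Among the 30, 7 were listed at 0 in GFP, and among the 6, 2 were listed at 0 in GFP_Tai, and these differ by construction. The median lay at percentile 100 of 10000 random lists matched on mean expression, a description of these libraries and no test of the genotypes. The share of higher genes was 58.8% in this list and 6.31% among all genes above the minimum. Cpr100A had FPKM 0.529 and 362. Edg78E had FPKM 0.327 and 318, from an estimated 1 fragment in GFP, a ratio of 972 with a 95% counting interval of 251 to 55289. The genes Lcp1, Lcp2, Lcp3 and Lcp4, which encode larval cuticle proteins, went the other way (named after their values were seen), unlike Lcp65Ad. Lcp1 had FPKM 30.0 in GFP and 1.76 in GFP_Tai, Lcp2 had 5.92 and 0.567, and Lcp3 and Lcp4 had 6.06 and 9.06 in GFP and were listed at 0 in GFP_Tai.

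Of the 23 genes of the Osiris list, 12 were above the minimum, all of them at least 2-fold higher in GFP_Tai, but the 7 listed at 0 in GFP are so by construction. The median log2 difference of the 12 was 2.95 (95% interval 1.99 to 4.28, percentile 100). Without the minimum, 52.2% of the list was at least 2-fold higher and the median was 1.14. Osi7 (3R:6248994-6251683 in BDGP6) rested on an estimated 5 fragments in GFP and 29768 in GFP_Tai, a ratio of 4559 with a 95% counting interval of 1952 to 14034. Osi6 (3R:6234708-6237181) rested on an estimated 1 and 8073 fragments, with a ratio of 5550 and an interval of 1109 to 244069. Osi9 had FPKM 0.7503 and 33.0, and Osi3 was listed at 0 in GFP and had 10.6 in GFP_Tai. In the authors' deposited table, Osi7 had p = 0.2439 and was not called.

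The ecdysone-response list, genes that answer the molting steroid, had 32 genes above the minimum. Of these, 11 were at least 2-fold higher and 0 lower, with a median log2 difference of 0.43 (95% interval 0.04 to 1.505, percentile 100). Edg78E and Edg84A, both among the 11, also belong to the cuticle protein list, so these lists overlap. ImpL1 had FPKM 4.39 and 538 (ratio 123, 95% counting interval 86.9 to 176). Cyp18a1, which encodes an ecdysteroid-inactivating enzyme, had 2.34 and 66.0 (ratio 28.2, interval 20.9 to 38.5). Among members chosen after their values were seen, the nuclear receptor gene ftz-f1 had FPKM 2.69 and 12.6, and Hr46, the file's name for Hr3, had 14.0 and 34.9. By contrast, the receptor gene EcR had 35.2 and 43.2, br had 315 and 297, and Eip74EF had 29.3 and 27.6. Lists of markers of other tissues also held some genes with higher values in GFP_Tai. Of 27 digestive protease genes (Jonah and trypsin families), 7 were above the minimum. Of these, 6 were listed at 0 in GFP, among them Jon65Aiv and Jon65Aiii, and so counted as higher by construction. The 3 salivary glue genes above the minimum rested on few fragments, an estimated 2 and 15 for Sgs3, 0 and 8 for Sgs7 and 0 and 4 for Sgs8 in GFP and GFP_Tai (median 1.85, and from 0.32 to 4.75 under the alternative settings), and the counting interval of Sgs8 included equal values. The trachea list had 3 of 11 genes higher and a median log2 difference of 0.41 (percentile 99.8). These were Gasp, with FPKM 90.9 and 328, and the chitin deacetylase genes serp, with 91.1 and 262, and verm, with 259 and 720, while the tracheal regulator genes trh and btl, chosen after their values were seen, had 21.3 and 20.2 and 3.47 and 3.45.

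**Figure D2:**
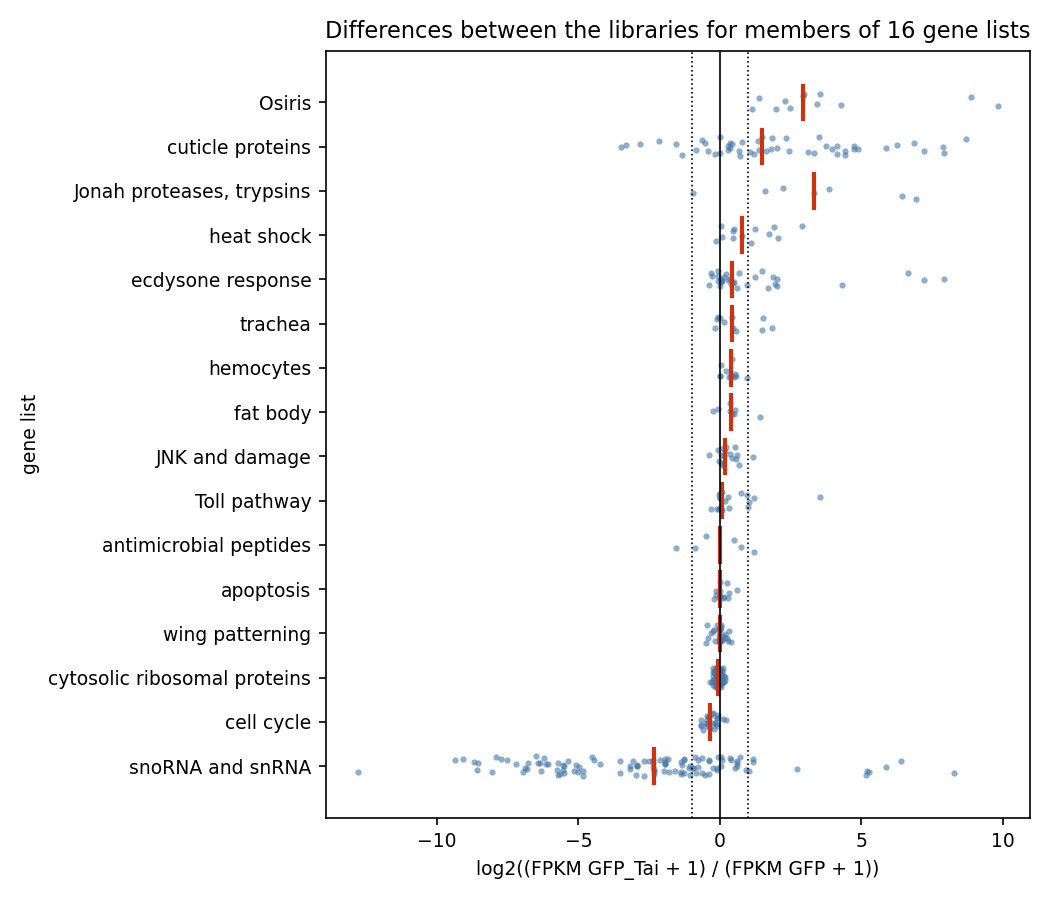
Log2 difference between the GFP_Tai and GFP libraries, on the log2(FPKM + 1) scale, for members of 16 gene lists with an FPKM of at least 1 in either genotype. Each point is 1 gene, red bars mark list medians, the solid line is 0 and the dotted lines a 2-fold difference. The Osiris median is 2.95, the cuticle protein median 1.48, the Toll pathway median 0.08 and the snoRNA and snRNA median -2.34.

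The title of the series names Toll signals and apoptosis, and the Toll and death genes were therefore compared. Of 20 Toll pathway genes above the minimum, 3 were at least 2-fold higher in GFP_Tai and 0 lower, with a median log2 difference of 0.08 (95% interval 0.01 to 0.76, percentile 91.4). The share of higher genes, 15%, was 25% with a pseudocount of 0.1 or after centring, since spz6 and spz lay just under the threshold, and 5% with a pseudocount of 5. The genes with the largest differences encoded Spätzle-family ligands and an NF-kB factor. The ligand gene spz4 had FPKM 0.159 and 12.4 (ratio 78.1, 95% counting interval 26.7 to 254), NT1 had 5.86 and 14.7 (ratio 2.51, interval 2.10 to 3.02), and spz6 had 12.8 and 26.5 (ratio 2.07, interval 1.72 to 2.52). The ligand gene spz had 1.93 and 4.74 (ratio 2.46, interval 1.59 to 3.91), and Dif, the NF-kB factor, had 3.49 and 8.24 (ratio 2.36, interval 1.80 to 3.13). The receptor gene Tl had 19.8 and 25.3, the inhibitor gene cact 73.5 and 74.3, and the NF-kB gene dl 26.7 and 27.9. In the authors' deposited table, spz had p = 0.5344 and Dif p = 0.54335, and neither was called.

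Among 12 genes of the extracellular steps upstream of Toll, 2 were higher and 1 lower (median 0.08, percentile 79.2). The sulfotransferase gene pip had FPKM 18.4 and 46.7, and the protease gene SPE had 4.69 and 1.26. Of 12 genes of the Imd pathway, the other immune NF-kB pathway, 1 was higher, the receptor gene PGRP-LC with 4.55 and 23.5 (ratio 5.17, interval 3.97 to 6.90). The median of that list was 0.13 (percentile 95.8). Of the 6 antimicrobial peptide genes above the minimum, 1 was higher and 1 lower (percentile 27.0). Their median was 0.01, but -0.19 with a pseudocount of 0.1 and 0.63 at a minimum of 5. Drs had 3.08 and 5.90 FPKM, from an estimated 4 and 11 fragments. Of 13 serpin genes, 1 was higher (median 0.09, percentile 88.0).

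None of the 13 apoptosis genes above the minimum was at least 2-fold different, and their median was 0.01 (95% interval -0.12 to 0.27, percentile 72.1). The death gene hid, listed under its older symbol W, had FPKM 32.7 and 50.03 (ratio 1.53, interval 1.402 to 1.67). The death gene rpr had 24.6 and 29.5 (ratio 1.20, interval 0.96 to 1.499), and Diap1, the inhibitor listed as th, had 233 and 281. The death gene grim was listed at 0 in GFP and had 0.127 in GFP_Tai. Of 17 JNK pathway and damage-response genes, 1 was higher (median 0.20, 95% interval 0.05 to 0.53, percentile 99.4). It was scaf, with FPKM 32.6 and 74.5, and the matrix protease gene Mmp1 had 33.9 and 50.1. The JAK/STAT list had 0 of 9 genes different (median -0.02, percentile 46.1), and the Hippo pathway list had 0 of 21 (median 0.00, percentile 79.4). The 4 cell competition genes had a median of 0.08 (percentile 85.7). Of 9 germline genes, 1 was higher, piwi with 0.690 and 2.97 (median 0.22, percentile 87.1).

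Genes of the cell cycle and DNA replication lay slightly lower in GFP_Tai. None of the 25 was at least 2-fold different, but 23 had a log2 difference below 0, and the median was -0.34 (95% interval -0.47 to -0.16, percentile 0). The replication clamp gene mus209 (PCNA) had FPKM 413 and 260, and the ribonucleotide reductase gene RnrS had 176 and 110. Mitochondrial ribosomal protein genes had a median of -0.18 over 71 genes (percentile 0.005), with 60 below 0 and 1 at least 2-fold lower. Cytosolic ribosomal protein genes had 0 of 87 at least 2-fold different and a median of -0.07 (percentile 71.3). The wing patterning list had 0 of 28 genes different (median -0.00, 95% interval -0.04 to 0.04, percentile 76.2), and the Notch and EGFR list had 0 of 18 (median -0.01, percentile 75.6).

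Most genes of the small nucleolar and small nuclear RNA list had lower values in GFP_Tai. The list, matched by symbol, had 114 genes above the minimum, among them 7 Uhg host genes and the protein-coding gene Psi. Of the list, 77 genes were at least 2-fold lower and 10 higher, with a median of -2.34 (95% interval -2.94 to -1.38, percentile 0), and 36 of the 77 were listed at 0 in GFP_Tai. Without genes listed at 0 in either genotype, a choice made after seeing the data, 57.7% were lower and the median was -1.27. Without the host genes and Psi, 77 of 106 were lower and 10 higher, with a median of -2.36. Of these 106 genes, 94 were snoRNAs. The median length of the 106 was 141 nt, below the 215 nt taken off each transcript length. Most of them therefore had no fragment estimate and no counting interval, and high FPKM values can rest on few fragments. Some shared the same ratio, such as 0.191 for snRNA:U4:39B, snoRNA:Psi28S-1175b and snoRNA:Psi18S-1854b, as small whole numbers of fragments would give. Genes named snRNA had listed values in both directions (examples chosen after their values were seen). These values too can rest on few fragments, so they do not settle a direction for snRNAs. The gene snRNA:U11 had FPKM 37.8 and 4.13, and snRNA:U4:39B had 153 and 29.3. By contrast, snRNA:U5:63BC and snRNA:U5:23D were listed at 0 in GFP and had 307 and 57.0 in GFP_Tai. The gene snmRNA:331, which the BDGP6 annotation names snRNA:7SKa, had FPKM 7134 in GFP and was listed at 0 in GFP_Tai, which can be a failed estimate. Both histone genes above the minimum had lower values too (median -2.18), His1:CG33834 with 31.2 and 5.93 and His4:CG33905 with 18.2 and 3.33. Values of such short or repeated genes are uncertain, since fragments can be shared between copies.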

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

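Leaving out genes at 0, the small RNA list, or its Uhg genes and Psi was chosen after seeing the data, and the other alternatives were planned. Of 408 alternative values for 52 results, 364 stayed within the limits set for each and 44 moved. The number of higher genes (522) was 284 with a pseudocount of 5, 813 at 1.5-fold and 324 at 3-fold. The number of lower genes (150) was 97 with a pseudocount of 5, 325 at 1.5-fold, 87 at 3-fold, 96 without genes listed at 0 and 73 without the small RNA list. The thresholds change these counts by construction. Without genes listed at 0, 1 of the authors' 11 calls was left. The log2 difference of tai (4.97) was 5.01 with a pseudocount of 0.1, 4.78 with 5 and 5.002 after centring.

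Without the filter, the median of the cuticle list (1.48) was 0, that of the small RNA list (-2.34) was 0 and that of the Osiris list (2.95) was 1.14, since many added members are at 0 in both genotypes. At a minimum FPKM of 5 the cuticle median was 3.41. The Osiris median was 5.32 with a pseudocount of 0.1 and 1.44 with 5, and the small RNA median was -1.27 without genes listed at 0. The share of cuticle genes at least 2-fold higher (58.8%) was 24.6% without the filter and 73.5% at a minimum of 5. For Osiris genes (100%) it was 66.7% with a pseudocount of 5 and 52.2% without the filter. Of the antimicrobial peptides (16.7%), 0% were higher with a pseudocount of 5, at a minimum of 5 and without genes at 0. Of the small RNAs, 67.5% were lower, and 24.2% without the filter and 57.7% without genes at 0. Their higher share (8.77%) was 3.14% and 4.23%. Causes not named were not tested. Among lists with other results, 14 values moved. The median subtracted in centring was -0.03, too small a shift to move a list median out of its limits. Leaving out replicates was not run. No paired analysis was possible because the table has 1 value per genotype.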

Other observations

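Apart from the test of protein-coding genes of short length, the tests below were chosen after the result they measure was seen.

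Of 13 heat shock genes above the minimum, 6 were at least 2-fold higher in GFP_Tai and 7 were not, with a median log2 difference of 0.77 (95% interval 0.08 to 1.91, percentile 99.99). Hsp68 had FPKM 22.01 and 85.3, Hsp22 had 12.6 and 44.8, and Hsp70Bc had 0.624 and 11.2. By contrast, members chosen after their values were seen lay near equal values, Hsp23 with 3587 and 3782, Hsp27 with 2823 and 2914, and Hsp83 with 1030 and 942. Hsp26, chosen in the same way, was among the 6 higher genes, with 421 and 899. Of 25 genes matched by the cytochrome P450 symbol pattern, which include the cyclophilin gene Cyp1, 8 were higher (median 0.33), among them Cyp303a1 with 1.17 and 19.96. The matrix protease gene Mmp2 had 16.4 and 34.3, and lactate dehydrogenase, listed as ImpL3, had 9.63 and 29.2. Markers of blood cells had a median of 0.40 over 12 genes (95% interval 0.03 to 0.53). Some of these lay near the minimum, such as Sr-CI with FPKM 0.474 and 1.87 and srp with 0.466 and 1.09. Fat body markers had 0.40 over 8 genes (95% interval -0.25 to 1.43), while myoblast markers had -0.03 and muscle genes -0.23. Some genes chosen after their values were seen stood out. The odorant-binding protein genes Obp56d (1.64 and 297) and Obp56a (95.0 and 12.1) differed in opposite directions. The small-peptide gene tal-AA had 17.6 and 181. The entry tal-1A, at the same coordinates, had 0.333 and 53.7, so the split of fragments between these entries is uncertain. The zona pellucida domain gene dy had 2.00 and 81.7.

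Genes at least 4-fold higher in GFP_Tai lay near each other. Of 236 placed genes, 70 had another such gene starting within 10 kb, where 10000 random lists of kept genes had a median of 20 and at most 45. The 70 include tal-1A and tal-AA, which have the same coordinates. The longest run, on 3R from 17413901 to 17446499 in BDGP6, held 6 genes, 3 of them called in the authors' deposited table (CG33333, CG42834 and CG14332). Families of neighboring related genes may account for part of this, which was not tested.

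The cuticle and Osiris genes that were higher in GFP_Tai were weighed against technical explanations. Counting error at low FPKM is argued against, since 46 of all 145 members of both lists, with no minimum applied, had a counting interval of the ratio above 1 and 7 below 1. That is 31.7% above (95% interval 24.3% to 40.0%), where counting error alone would put 2.5%, and of 54 members with fragments in both libraries, 30 lay above and 5 below. Carry-over of epidermis making larval cuticle cannot be told apart, because 4 of the 7 Lcp genes above the minimum were at least 2-fold lower and the other 3 at least 2-fold higher. Older discs in the GFP_Tai pool cannot be told apart from an effect of Tai, because no age within the wandering stage is recorded. Ecdysone-response genes higher and cell cycle genes lower (median -0.34) could go with either, and an effect of Tai stays open and untested.

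The lower values of the small nucleolar and small nuclear RNA list were weighed in the same way. Counting error was left out, since most of these small RNAs have no fragment estimate. Lower expression of the host genes of snoRNAs is argued against for 86 of the 106 small RNA genes, snoRNAs lying within another gene on the same strand. Their 30 host genes had a median log2 difference of -0.119 (95% interval -0.18 to -0.08, lowest -0.84). The 86 had -2.35 (-3.53 to -1.83), and the 52 of them above 0 in both genotypes had -1.36. Many of the 86 share a host gene, so they are not independent. The other 20 were not tested. Loss of short transcripts of every kind cannot be told apart: 58 protein-coding genes with transcripts under 400 nt had a median of 0.037, but only 4 of the small RNAs reached 266 nt, the 5th percentile of the lengths of those genes, so the bound set beforehand covers too few of them. Less RNA without a poly(A) tail in GFP_Tai stays open too, since the 2 histone genes and the RNase P and MRP RNAs had a median of -2.46, but these are few and their values had been seen. A biological difference in small RNAs between the genotypes was not tested.

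The authors' calls other than tai were all listed at 0 in GFP. That the size of the difference alone set the calls is argued against, since 30 uncalled genes above 0 in GFP had a counting interval of the ratio above that of tai, which reached 34.0 and was called in the authors' deposited table. An average over 3 separately scaled libraries per genotype is argued against, because 75.2% of low genes lay at ratios of whole numbers times 1 common factor. Pooling of fragments before scaling stays open, and whether a listed 0 itself bears on a call was not tested.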
